A study of Homo sapiens with 48 samples.

How the data were processed

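Gene expression was measured by RNA sequencing in THP-1, a human monocytic leukemia cell line. Per the labels, the libraries were made from 500 ng of total RNA with a Lexogen Quant-Seq kit. The cells had been kept with a chemical, with the vehicle dimethyl sulfoxide (DMSO) or with neither for 12 h. The deposited files hold whole-number counts per gene symbol for each of 48 libraries, with no header on how they were made. The submitters' processing notes name Bowtie2, bedtools and the human genome build hg19, also called GRCh37. They give no versions, and the role of each tool, the annotation and whether counting used strand are not given in the sources used here. The submitters' design text names edgeR for their own differential expression. Each file lists the same 25737 rows. A total of 286 symbols occur on several rows (1561 rows, 1.36% of all counts), and these rows were summed, which left 24462 symbols. Every row carries a symbol, and genes are named by the symbols of the files.

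Groups were taken from the labels. There are 12 treatments with 3 libraries each, 6 vehicle libraries and 6 untreated libraries. The vehicle and untreated libraries each carry a series number, 1 or 2, with 3 libraries per series, and the labels do not say which series belongs to which treatment. Nothing in the labels says that the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Within groups, 48 pairs of libraries were compared by a chi-square test of their counts. The ratio of chi-square to its degrees of freedom was between 2.18 and 46.0, no pair was identical, and every library was kept as 1 replicate.

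The gene-wise test was edgeR's quasi-likelihood F-test (edgeR 4.0.16 in R 4.3.3) on the counts as deposited, with TMM scaling. Genes were kept by filterByExpr, which left 15642. All 48 libraries in 16 groups entered 1 fit, so that the groups share the estimate of spread (32 residual degrees of freedom, common biological coefficient of variation 0.122). Each treatment was tested against vehicle series 1 and against vehicle series 2. The larger of the p-values was kept where both changes had the same sign and the p-value was set to 1 elsewhere. The p-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene is said to be called, or to have risen or fallen, at an adjusted p under 0.05. The log2 fold change of a treatment is the mean of its values against both vehicle series. Its standard error (SE) is the size of that mean divided by the square root of its F statistic. This SE does not cover the difference between the vehicle series. Expression levels are CPM of the TMM-scaled library, as mean ± SD over the 3 treated or the 6 vehicle libraries unless another n is given. Direct comparisons of treatments, vehicle against untreated libraries and control series 2 against control series 1 were each 1 contrast of the same fit.

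Genes named in the text follow a rule. Among called genes with a mean log2 fold change of at least 1 in size, a mean of at least 5 CPM on one side and every treated library beyond all 6 vehicle libraries, it takes the 6 largest rises and the 6 largest falls (5 of each in direct comparisons). It adds up to 4 called members with the largest change from each called gene list. Other members of those lists are named with their values. Some genes that the rule names are not reported here. The groups, the tests, this rule, the gene lists named in the design and the alternatives were fixed before the data were examined, apart from 4 alternatives added later. Of 26 fixed gene lists, 21 were tested in each of 12 treatments with camera in limma 3.58.1 at a preset correlation of 0.01, with the same rule over both vehicle series, and adjusted over the 252 tests. The other lists had under 5 tested members: the mitochondrially encoded genes, which are not reported here, and the T cell, epithelial, fibroblast and erythroid markers. Marker lists of other cell types, that of B cells included, are given as summed CPM of the unscaled totals. Single markers of other cell types and MALAT1 are also given as CPM of the unscaled totals. Of 43 list calls, 31 hold when camera estimates the correlation, and the text gives that adjusted p where a call is lost. List counts are given over all genes and adjusted over the list alone.

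Total counts per library, in mega-counts (M), were 5.95 M to 11.5 M. The tests were tried on simulated data for the aciclovir comparison, in which 67 genes were changed 1.5-fold, 67 genes 2-fold and 66 genes 4-fold. With the simulated treatment at vehicle series 1, it recovered 40.3% of 1.5-fold, 64.2% of 2-fold and 93.9% of 4-fold changes, with 2 false calls among 135 over 15388 genes. With the treatment midway between the vehicle series, it recovered 23.9%, 64.2% and 98.5%, with 0 false calls among 125 over 15397 genes. Every simulated library was drawn with a spread set by the level of the gene alone. These values therefore do not carry over to groups with a wider spread or a library that stands apart. Counting intervals (95%) and floors cover counting error only. A fold against a group with no counts is a lower bound against a floor of 3 counts over that group. Genes that share sequence with a near-identical copy, genes that overlap or run antisense to another gene, and genes of the major histocompatibility complex are marked as uncertain, since reads could be split between them.

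Alternatives were RLE size factors, no filter on low counts, a filter at 5 CPM, limma-voom, DESeq2 1.42.0, a replicate block, each vehicle series alone, the 6 vehicle libraries as 1 group, untreated in place of vehicle libraries, fits of a treatment and both vehicle series alone, a 2-fold threshold, and leaving out each library in turn. Annotation from GENCODE for build GRCh38 was used only to find neighbouring genes by symbol. Figures were drawn with matplotlib 3.10.9. No GC or gene length check was made, since the annotation behind the counts is not given in the sources used here.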

Results

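RNA was sequenced from THP-1 cells, a human monocyte-like leukemia line, after 12 h with 1 of 12 chemicals. Per the labels, each chemical was given at its CV90, a term in use for the concentration that leaves 90% of cells viable, and the concentrations themselves are not given in the sources used here. The chemicals were the bacterial cell wall component lipopolysaccharide (LPS), the glucocorticoids dexamethasone and prednisolone, the calcineurin inhibitors cyclosporine and tacrolimus, and the nucleoside analogues aciclovir and ribavirin. The others were the JAK kinase inhibitor tofacitinib, the detergent sodium lauryl sulfate, mercuric chloride, the plant isoflavone genistein and the preservative benzoic acid. Each was measured in 3 libraries, beside 6 vehicle and 6 untreated libraries that each come in series 1 and series 2 with 3 libraries per series. The protocol gives 0.1% DMSO for the vehicle, while the titles of the 6 vehicle libraries give 0.1, 0.2 and 0.3% in series 1 and 0.4, 0.5 and 0.6% in series 2. Total counts per library, in mega-counts (M), were 5.95 M (mercuric chloride replicate 2) to 11.5 M (ribavirin replicate 1). Group means were lowest with mercuric chloride, at 6.41 ± 0.508 M (SD, n = 3), and highest with genistein, at 10.9 ± 0.55 M (SD, n = 3). The mercuric chloride libraries had counts in 18748 ± 211 gene symbols, against 16310 to 16945 symbols as the means of the other 15 groups, and their 10 most abundant genes took 12.0% of the counts against 5.58 to 6.02% elsewhere.

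The first comparison asked whether the control series differed from each other, since every treatment is set against both. Of 15642 genes tested, 4716 differed between the control series, 2346 higher and 2370 lower in series 2. Among genes of the NRF2 oxidative stress response, which protect cells against oxidants, 17 of 20 were higher in series 2 over all genes and 18 adjusted over the list alone (adjusted p = 3.09e-19). HMOX1, which encodes the heme-degrading enzyme heme oxygenase 1, was higher by a log2 fold change of 1.22 (adjusted p = 0.000359), and the cystine transporter gene SLC7A11 by 1.58 (adjusted p = 3.63e-19). Metallothionein genes, which bind zinc and other metals, were higher for 7 of 9 members both over all genes and adjusted over the list alone (adjusted p = 3.73e-09). Interferon-stimulated genes were higher for 11 of 24 and lower for 1 by both adjustments (adjusted p = 1.9e-05). G2/M cell cycle genes were higher for 11 of 19 and lower for 1, and adjusted over the list alone 12 were higher and 2 lower (adjusted p = 3.27e-06). Integrated stress response genes (10 of 20 higher and 3 lower, 10 and 5 adjusted over the list alone, adjusted p = 0.0191, and adjusted p = 0.0624 with an estimated correlation), cholesterol genes (7 of 21 higher by both adjustments, adjusted p = 0.00819, and adjusted p = 0.138 with an estimated correlation) and ribosome biogenesis genes (7 of 18 higher and 4 lower, 8 and 4 adjusted over the list alone, adjusted p = 0.019, and adjusted p = 0.174 with an estimated correlation) were called as higher too. The largest differences between the series by the naming rule were PLS3, an actin-bundling protein gene, at 4.36 ± 0.50 (log2, SE, n = 6 per series) and LOC344887 at 4.05 ± 0.45, with DLX3 (2.62) and TRIM16L (2.58). PRLR, the prolactin receptor gene, fell from 14.9 ± 1.55 to 4.76 ± 0.872 CPM in series 2 (log2 -1.65, SE 0.22), beside GRIA3 (-1.87) and HIST1H2BC (-1.65), while SPATA31C1 and SPATA31C2 (log2 -3.13 and -3.27) are near-identical copies and uncertain. In the untreated libraries alone 2225 genes differed between the series and in the vehicle libraries alone 2983, and all 1620 genes called in both moved in the same direction.

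Treatments therefore differ in their distance to each series, and genes are called here only where a treatment differed from both. On an axis set by the untreated libraries, with the mean of vehicle series 1 at 0 and that of vehicle series 2 at 1, cyclosporine lay at 1.04 ± 0.02 and mercuric chloride at 1.13 ± 0.04 (SD, n = 3 each). The other 10 treatments lay between -0.05 (aciclovir) and 0.31 (benzoic acid). The axis takes in all genes, those that respond included, so a response can also move a position. Mercuric chloride called 8985 genes against vehicle series 1 alone and 8221 against series 2 alone, and cyclosporine 3762 and 218. Replicate 3 of benzoic acid lay at 0.64, apart from the other replicates, and replicate 3 of dexamethasone differed most from its group among all 48 libraries (0.901 as root mean square log2 distance to the others).

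**Figure D1:**
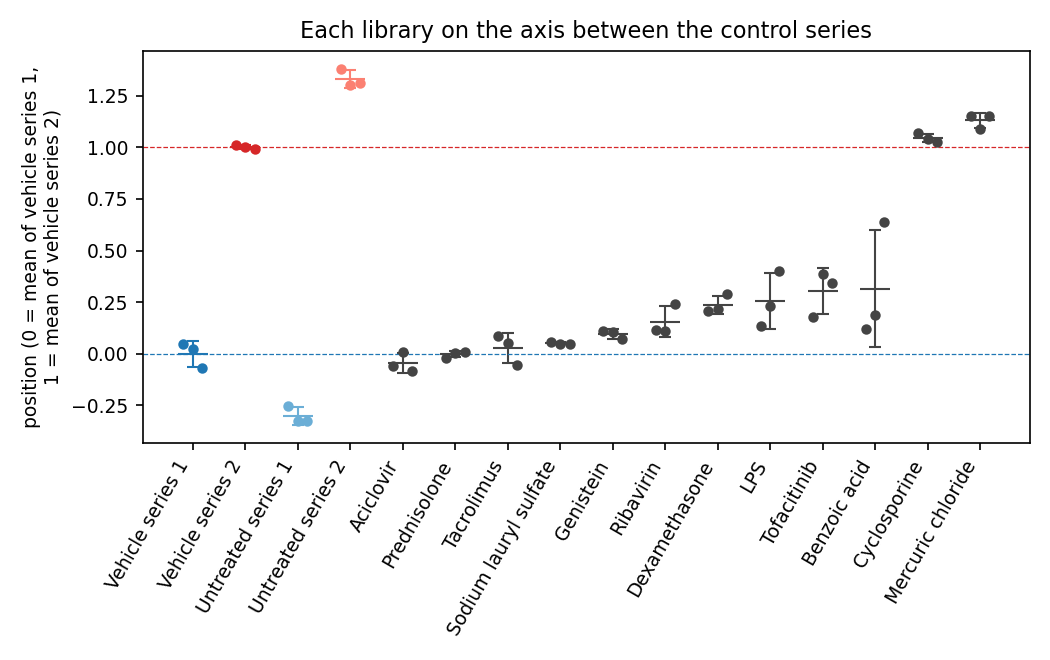
Position of each library (points), with the mean and SD of each group of 3 (bars), on an axis on which the mean of vehicle series 1 is 0 and that of vehicle series 2 is 1. Cyclosporine (1.04) and mercuric chloride (1.13) lie near 1, and the other treatments lie nearer to 0. The axis takes in all genes, so a response can also move a position.

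Vehicle and untreated libraries were compared to see what the solvent alone did. Metallothionein and zinc export genes were lower as a list in vehicle libraries (9 tested, median log2 -0.31, adjusted p = 7.4e-10). None of the 9 was called over all genes and 6 were lower adjusted over the list alone. The NRF2 list had a median of -0.09 over 20 genes with 0 called by either adjustment (adjusted p = 0.00118, and adjusted p = 0.174 with an estimated correlation). Over all genes, edgeR called 0 of 15642, with 463 at an unadjusted p under 0.05, and limma-voom and DESeq2 also called 0. The vehicle effect differed between the series for 0 genes by edgeR (514 at an unadjusted p under 0.05).

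**Figure D2:**
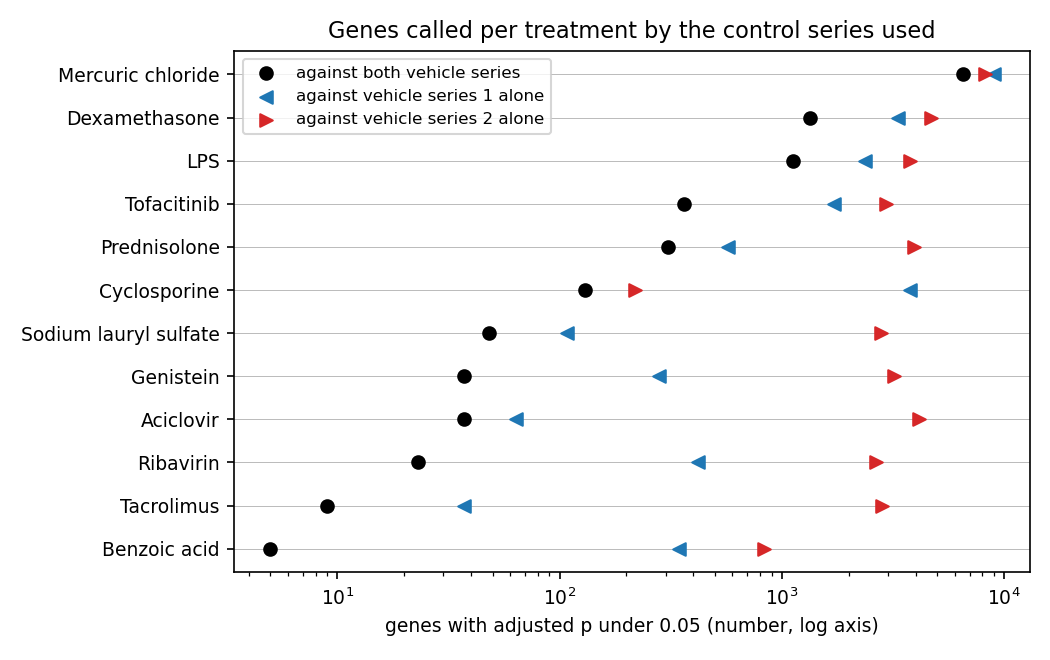
Number of genes with an adjusted p under 0.05 for each treatment (log axis), against both vehicle series (circles), vehicle series 1 alone (left-pointing triangles) and vehicle series 2 alone (right-pointing triangles). Against both series the counts run from 5 (benzoic acid) to 6549 (mercuric chloride).

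LPS raised the inflammatory program of the cells. Of 25 NF-kB inflammatory response genes, 24 rose, both over all genes and adjusted over the list alone (median log2 3.64, adjusted p = 1.46e-42). The IL-27 subunit gene EBI3 rose from 0.25 ± 0.218 to 57.8 ± 5.61 CPM (log2 7.81, SE 0.45), ICAM1, an adhesion molecule gene, by 6.71 ± 0.43 (log2, SE), and the cytokine genes IL1B and TNF by 5.72 and 3.64, with TNF uncertain as a gene of the major histocompatibility complex. The chemokine gene CCL4 (log2 9.58, SE 0.62) and its copies CCL4L1 (7.47) and CCL4L2 (7.16) share nearly identical sequence, so their separate values are uncertain. The cytokine genes IL32 (7.86, SE 0.63) and CXCL13 (7.48, SE 0.98) were also among the 6 largest rises. Interferon-stimulated genes rose for 12 of 24 members, and for 15 adjusted over the list alone (adjusted p = 6.42e-08). Among these, CXCL10 had 106 counts against 0 in the 6 vehicle libraries, which makes it at least 64.8-fold higher, and the antiviral gene OAS3 rose from 13.7 ± 4.7 to 88.2 ± 9.88 CPM (log2 2.75, SE 0.14).

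Macrophage maturation genes rose for 8 of 18 members with LPS, and for 11 adjusted over the list alone (adjusted p = 2.85e-06). The matrix protease gene MMP9 rose by 5.85 ± 0.35 (log2, SE) and the scavenger receptor gene CD36 by 1.82 ± 0.11. Antigen presentation and costimulation genes rose for 5 of 15, and for 6 adjusted over the list alone (adjusted p = 1.97e-06), with the costimulatory receptor gene CD40 at 2.76 ± 0.22 and CD74 at 1.21 ± 0.08. HLA-DRA rose by 1.47 ± 0.14 and is uncertain as a gene of the major histocompatibility complex. Of 7 aryl hydrocarbon receptor targets, 3 rose, and 4 adjusted over the list alone (adjusted p = 9.18e-05), with CYP1B1 going from 185 ± 20 to 620 ± 68.6 CPM. Immediate early and calcineurin-NFAT genes rose for 4 of 16 by both adjustments (IER3 4.98, JUN 1.75, JUNB 1.13 and KLF6 0.95, adjusted p = 0.000266). IER3 is uncertain as a gene of the major histocompatibility complex. The p53-linked stress genes that rose were BTG2 (3.39), BBC3 (1.10), CDKN1A (1.08) and MDM2 (0.48), 4 of 16 by both adjustments (adjusted p = 0.00529). JAK-STAT feedback genes rose for 7 of 16 and CISH fell (log2 -0.96), and adjusted over the list alone 8 rose and 2 fell (adjusted p = 0.00628). That call is lost when the correlation is estimated (adjusted p = 0.0537 with an estimated correlation).

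Among genes lower with LPS, the plasminogen activator inhibitor gene SERPINB2 fell from 40.5 ± 15.1 to 6.26 ± 2.51 CPM (log2 -2.62, SE 0.23) and SERPINB10 by 2.99 ± 0.30 (log2, SE). RASGRP2, an activator of Rap GTPases, fell from 127 ± 14.6 to 30.6 ± 1.52 CPM, and the 6 largest falls also held DACH1 (-2.22), STAR (-1.94) and TUBA4A (-1.91). The summed CPM of T cell markers was 35.8 ± 2.75 with LPS against 3.66 ± 0.798 and 3.34 ± 1.05 in vehicle series 1 and 2 (SD, n = 3 each), nearly all of it from the interleukin 7 receptor gene IL7R (35.4 ± 2.75 CPM), while CD3E had 0 counts. In all, 1127 genes were called with LPS, 714 higher and 413 lower, against 2376 with vehicle series 1 alone and 3772 with vehicle series 2 alone.

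Dexamethasone raised the targets of the glucocorticoid receptor. Of 20 such genes, 12 rose over all genes and 13 adjusted over the list alone (median log2 1.21, adjusted p = 7.88e-14). TSC22D3, which encodes the anti-inflammatory protein GILZ, rose from 27.6 ± 5.49 to 623 ± 72.5 CPM (log2 4.51, SE 0.11). The transcription factor gene ZBTB16 rose by 6.52 ± 0.41 (log2, SE), the adenosine receptor gene ADORA3 by 5.19 ± 0.29 and the hemoglobin scavenger receptor gene CD163 by 4.25 ± 0.67. The protease gene MMP7 had 191 counts against 0 in the 6 vehicle libraries, at least 131-fold higher. CYP19A1, which encodes the estrogen-producing enzyme aromatase, rose from 0.265 ± 0.192 to 22.9 ± 4.05 CPM (log2 6.41, SE 0.43), beside ARMC12 (6.71), GLDN (5.61) and UNC13C (5.27).

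Cholesterol synthesis and uptake genes rose for 10 of 21 members with dexamethasone, and for 13 adjusted over the list alone (adjusted p = 1.1e-05). The last-step synthesis gene DHCR7 went from 8.27 ± 0.988 to 20.3 ± 3.82 CPM, with STARD4 at 1.28 ± 0.20 (log2, SE) and MVK at 1.09 ± 0.18. Of 16 p53-linked stress genes, 4 rose by both adjustments (CDKN1A 1.46, SESN1 1.40, BBC3 0.69 and MDM2 0.39, adjusted p = 0.00639). Immediate early and calcineurin-NFAT genes rose for 6 of 16, and for 7 adjusted over the list alone (adjusted p = 0.00729, and adjusted p = 0.12 with an estimated correlation). They were led by the uncertain IER3 (1.89), JUN (0.93), KLF6 (0.84) and IER2 (0.71). The NF-kB inflammatory response list was not called (adjusted p = 0.0568), although 7 of its 25 members rose, and 9 adjusted over the list alone, among them the NF-kB inhibitor gene NFKBIA (1.85) and the uncertain TNF (1.90). The largest falls were SERPINB2 (log2 -3.59, SE 0.26), WNT7B (-2.80, SE 0.19), SERPINB10 (-2.27, SE 0.28), SLC7A11 (-1.88, SE 0.11) and the interferon-induced gene HERC5 (-1.87, SE 0.24). SLC7A11 was also higher in control series 2, so the size of its fall depends on the vehicle series. NDUFC2-KCTD14 (-2.69, SE 0.63) overlaps its neighbours and is uncertain.

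In all, 1340 genes were called with dexamethasone, 780 higher and 560 lower, against 3345 with vehicle series 1 alone and 4718 with vehicle series 2 alone. The spread between dexamethasone libraries (median SD of 0.314 on the log2 CPM scale) exceeded that of the other groups (0.129 to 0.231), which the shared estimate does not take up, and without dexamethasone replicate 3 the count was 832. In a fit of the 9 libraries compared alone it was 511. Thinned to equal depth, dexamethasone replicate 3 had counts in 15247 symbols, the fewest of all 48 libraries, against 16312 and 16346 in replicates 1 and 2.

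Prednisolone raised glucocorticoid receptor targets as well. Of 20 genes, 11 rose over all genes and 12 adjusted over the list alone (median log2 1.15, adjusted p = 1.47e-15). ZBTB16 rose by 4.57 ± 0.43 (log2, SE), ADORA3 by 4.33 ± 0.30, CD163 by 3.94 ± 0.68 and the clock gene PER1 from 4.9 ± 1.16 to 62.7 ± 6.34 CPM (3.68, SE 0.19). The largest rise was CYP19A1, from 0.265 ± 0.192 to 31.9 ± 1.86 CPM (log2 6.89, SE 0.42), and ARMC12 (5.91), GLDN (5.15) and UNC13C (4.62) were also among the 6 largest. SLC7A11 fell by 1.80 ± 0.11 (log2, SE), WNT7B by 1.75 ± 0.17 and SERPINB2 by 1.57 ± 0.21. The size of the fall of SLC7A11, which was also higher in control series 2, depends on the vehicle series. The calcium-binding protein gene S100A8 fell from 83.9 ± 25 to 29.2 ± 4.32 CPM, and the other largest falls were KIAA1407 (-1.52) and EPHB1 (-1.47). With prednisolone 307 genes were called, 208 higher and 99 lower, against 574 with vehicle series 1 alone, 3939 with vehicle series 2 alone and 693 in a fit of the 9 libraries compared alone.

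Dexamethasone is prednisolone with an added fluorine and an added methyl group, and a direct comparison asked where their responses differ, at concentrations that are not given and may differ. The glucocorticoid receptor target TSC22D3 was higher with dexamethasone by 0.94 (log2, 95% interval 0.71 to 1.18), ZBTB16 by 1.95 (1.18 to 2.73), FKBP5 by 0.55 (0.33 to 0.78) and ADORA3 by 0.87 (0.29 to 1.45). For PER1 the difference was 0.21 (-0.19 to 0.61, adjusted p = 0.55) and for CYP19A1 it was -0.48 (-1.19 to 0.23), so neither was called. As a list, 6 of 20 targets were higher with dexamethasone by both adjustments (adjusted p = 0.0203, and adjusted p = 0.12 with an estimated correlation). Cholesterol synthesis and uptake genes were higher for 13 of 21, and for 14 adjusted over the list alone (adjusted p = 9.07e-12). Integrated stress response genes were higher for 7 of 20, and for 9 adjusted over the list alone (adjusted p = 0.000341), and immediate early genes for 6 of 16 by both adjustments (adjusted p = 0.000755, and adjusted p = 0.0497 with an estimated correlation). Purine nucleotide synthesis genes were lower for 4 of 15, and for 7 adjusted over the list alone (adjusted p = 6.85e-05). Endoplasmic reticulum chaperone genes were lower for 2 of 16 (PDIA4 -0.76 and CALR -0.35), and for 5 adjusted over the list alone (adjusted p = 0.0186, and adjusted p = 0.12 with an estimated correlation). DNA replication genes were lower for 2 of 20 (MCM6 -0.39 and CDC6 -0.31), and adjusted over the list alone 4 were lower and 1 higher (adjusted p = 0.0467, and adjusted p = 0.0641 with an estimated correlation). TBC1D30 (2.39, SE 0.26), EGR1 (1.65, SE 0.23) and CTGF (1.54, SE 0.43) were higher with dexamethasone, as was TNF (1.85, SE 0.22), which is uncertain. SERPINB2 (-2.02, SE 0.30), NT5M (-1.94, SE 0.42), the histone gene HIST1H1C (-1.54, SE 0.12) and PRDM6 (-1.38, SE 0.33) were lower, as was H3F3AP4 (-1.48, SE 0.41), an uncertain pseudogene.

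In all, 1444 genes differed between the glucocorticoids, 857 higher and 587 lower with dexamethasone, and 9935 of the 14198 genes not called had an interval within 2-fold either way. This count rests on single libraries: it was 2346 without dexamethasone replicate 2, 638 without dexamethasone replicate 3, 733 without prednisolone replicate 1 and 685 without prednisolone replicate 3. In a fit of these 6 libraries alone, added after the data were seen, it was 6, so not every gene named for this comparison is called there. Of the 857 higher genes 372 were also higher in control series 2 (129 if independent), and of the 587 lower genes 226 were lower there (88.9 if independent), counts added after the values were seen. The cholesterol and integrated stress response lists were also called higher in control series 2. Dexamethasone lay at 0.24 and prednisolone at -0.003 on the axis between the series, so a part from the series stays open for these lists. Cholesterol genes also rose with dexamethasone against both vehicle series.

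Against vehicle, the same genes were called with both glucocorticoids in 190 cases higher and 81 lower. Independent lists of these sizes would share 10.4 and 3.54 genes. Unchanged groups simulated against the same controls had 0 genes called, so they give no comparison for this overlap. With a different vehicle series for each drug, 519 higher and 292 lower genes were shared (213 and 208 if independent), or 278 and 162 with the series exchanged (48.9 and 37.6 if independent). Across genes, which are not independent replicates, the log2 fold changes of both drugs had a Pearson correlation of 0.509 and a covariance of 0.224, against 0.354 and 0.0299 for simulated unchanged groups. The simulated groups were placed at the mean of the vehicle series. Dexamethasone lay at 0.24 and prednisolone at -0.003 on the axis between those series. The simulated changes were also computed by another formula, from group sums with a small count added, which shrinks changes at low counts. Their spread was set by the level of the gene alone. The excess over the simulation can thus come from these settings and from that position as well as from the drugs. With separate vehicle series the correlation was 0.197 or 0.286 and the covariance 0.110 or 0.145. Of the 271 shared genes, 210 changed more with dexamethasone (median size 1.17 against 0.90, log2).

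**Figure D3:**
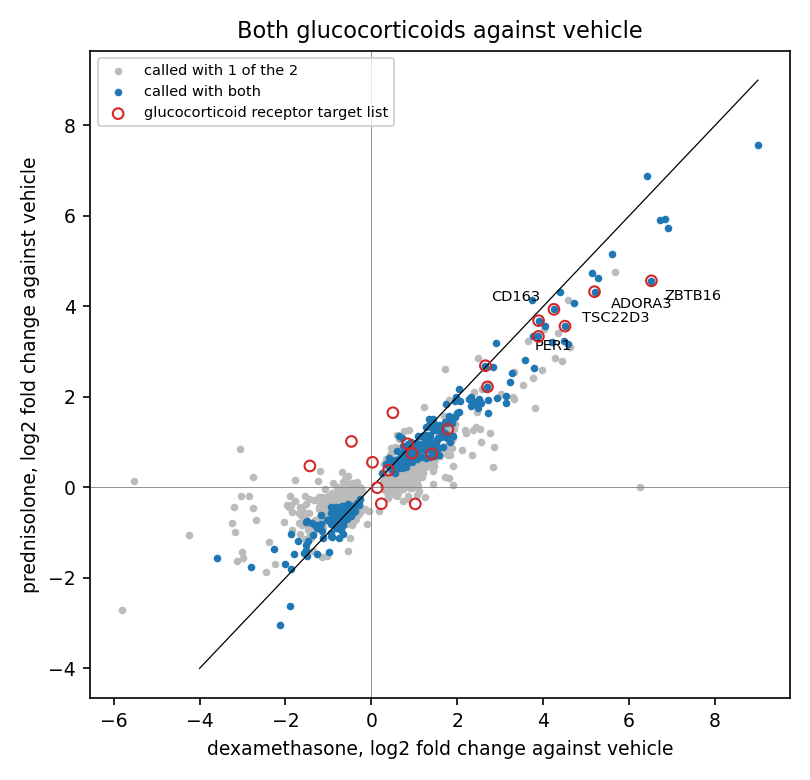
Log2 fold change of each gene called with either glucocorticoid, dexamethasone on the horizontal and prednisolone on the vertical axis, both as the mean against both vehicle series. Blue points are the 271 genes called with both, grey points those called with one, red circles the glucocorticoid receptor target list (called or not), and the line marks equal change.

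Cyclosporine raised genes of the integrated stress response, the program that the transcription factor ATF4 drives when translation is slowed. Of 20 such genes, 14 rose, both over all genes and adjusted over the list alone (median log2 1.20, adjusted p = 9.01e-17). The glutathione-degrading enzyme gene CHAC1 rose from 4.31 ± 1.22 to 33.1 ± 5.04 CPM (log2 2.94, SE 0.18), the secreted hormone gene STC2 by 3.10 ± 0.34, SESN2, a restraint on growth signalling, by 1.94 ± 0.12 and NUPR1 by 1.73 ± 0.19. Endoplasmic reticulum chaperone genes rose for 10 of 16, and for 14 adjusted over the list alone (adjusted p = 5.62e-11). HSPA5, which encodes the main chaperone of that compartment, went from 925 ± 68.4 to 1814 ± 68.9 CPM (log2 0.97, SE 0.06), beside HYOU1 (1.21, SE 0.08), CRELD2 (1.10, SE 0.07) and SDF2L1 (0.76, SE 0.12). Of 20 NRF2 genes, SLC7A11 (1.38), GCLM (0.81) and FTH1 (0.52) rose, 3 over all genes and 10 adjusted over the list alone (adjusted p = 3.31e-06, and adjusted p = 0.0676 with an estimated correlation). The size of the rise of SLC7A11, which was also higher in control series 2, depends on the vehicle series. Purine nucleotide synthesis genes were lower as a list (15 genes, median log2 -0.19, adjusted p = 0.0156, and adjusted p = 0.0548 with an estimated correlation), with 0 called by either adjustment. Also among the 6 largest rises were ADM2 (2.27), ULBP1 (1.88) and MAP1B (1.87), and the falls named by the rule were SERPINB2 (-1.49), C16orf74 (-1.19) and ADAMTS1 (-1.14). With cyclosporine 130 genes were called, 110 higher and 20 lower, against 3762 with vehicle series 1 alone and 218 with vehicle series 2 alone. The count was 71 without cyclosporine replicate 1 and 85 without replicate 1 of vehicle series 2, but 401 in a fit of the 9 libraries compared alone and 259 without the pair of libraries that stand apart (dexamethasone replicate 3 and benzoic acid replicate 3, left out after the data were seen).

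Tacrolimus lowered cholesterol synthesis and uptake genes. The list was lower (21 genes, median log2 -0.38, adjusted p = 1.83e-08), with 2 called over all genes and 9 adjusted over the list alone. INSIG1, a sterol-regulated brake on this pathway, fell from 53.2 ± 4.6 to 31.7 ± 1.98 CPM (log2 -0.74, SE 0.11) and the squalene synthase gene FDFT1 by 0.39 ± 0.07 (log2, SE). Integrated stress response genes rose for 2 of 20, and for 4 adjusted over the list alone (adjusted p = 0.0345, and adjusted p = 0.0744 with an estimated correlation), with CHAC1 at 1.58 ± 0.19 and SESN2 at 0.89 ± 0.13. Ribosome biogenesis genes were lower as a list (18 genes, median log2 -0.21, adjusted p = 2.07e-05), with 0 called by either adjustment. With tacrolimus 9 genes were called, 4 higher and 5 lower, against 37 with vehicle series 1 alone and 2829 with vehicle series 2 alone. The hormone gene ADM2 also rose, by 1.45 ± 0.19 (log2, SE). The remaining 4 called genes, ID2 (0.41), CYCS (-0.33), TFRC (-0.98) and TIMP3 (-0.67), are named because the count is short and were chosen after their values were seen. Leaving out a library gave 5 (tacrolimus replicate 1 or 3, or replicate 3 of vehicle series 1) or 4 calls (tacrolimus replicate 2, or replicate 1 of vehicle series 2), while a fit of the 9 libraries compared alone gave 42 and leaving out the pair that stands apart gave 19.

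The calcineurin inhibitors, which differ in structure, were compared directly, at concentrations that are not given and may differ. Integrated stress response genes were higher with cyclosporine for 14 of 20 and lower for 1 by both adjustments (adjusted p = 8.38e-10), with CHAC1 at 1.36 and SESN2 at 1.05 (log2). Endoplasmic reticulum chaperone genes were higher for 13 of 16, and for 14 adjusted over the list alone (adjusted p = 2.26e-15), HYOU1 by 1.00 (95% interval 0.80 to 1.20) and HSPA5 by 1.15 (SE 0.08). Cholesterol genes were higher for 12 of 21, and for 15 adjusted over the list alone (adjusted p = 1.55e-09). NRF2 genes were higher for 16 of 20 by both adjustments (adjusted p = 3.09e-19), with OSGIN1 at 3.42, SLC7A11 at 1.99 and HMOX1 at 1.20. Interferon-stimulated genes were higher for 8 of 24, and for 9 adjusted over the list alone (adjusted p = 0.00165, and adjusted p = 0.0775 with an estimated correlation), and metallothionein genes for 6 of 9 by both adjustments (adjusted p = 0.000793, and adjusted p = 0.0929 with an estimated correlation). G2/M genes were higher for 9 of 19 and lower for 3, or 10 and 3 adjusted over the list alone (adjusted p = 0.0163, and adjusted p = 0.0969 with an estimated correlation). Ribosome biogenesis genes were higher for 7 of 18 and lower for 2, or 8 and 3 adjusted over the list alone (adjusted p = 0.00703, and adjusted p = 0.12 with an estimated correlation). Heat shock genes were lower for 7 of 16 and higher for 1, or 9 and 2 adjusted over the list alone (adjusted p = 0.0187, and adjusted p = 0.115 with an estimated correlation). The NRF2, metallothionein, interferon-stimulated, G2/M, ribosome biogenesis, cholesterol and integrated stress response lists were also called higher in control series 2 than in series 1. For them this comparison does not separate the drugs from the series. The endoplasmic reticulum chaperone and heat shock lists were not called between the series, though single members differed there. In series 2, 2 of 16 chaperone genes were higher and 8 lower, while 13 were higher with cyclosporine. Of 16 heat shock genes, 4 were higher and 3 lower in series 2. For the heat shock genes this comparison does not separate the drugs from the series either.

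LOC344887 (3.89, SE 0.58), PLS3 (3.46, SE 0.64), and BEX5 (2.74, SE 0.48) were among the 5 genes most raised with cyclosporine over tacrolimus, beside OSGIN1. TMEM52B (-2.13, SE 0.44), LOC100506472 (-1.88, SE 0.44) and RGCC (-1.72, SE 0.49) were lower. The transcription factor gene FOS was lower with cyclosporine (log2 -1.68, SE 0.31), as was NPTX1 (-1.66, SE 0.15), while EGR1 was not called (0.48, 95% interval -0.04 to 1.00). In all, 3152 genes differed, 1707 higher and 1445 lower with cyclosporine, or 2101 without tacrolimus replicate 3. Of the 12490 genes not called, 8232 had an interval within 2-fold either way. The drugs lie at opposite ends of the axis between the control series, and 1388 of the 1707 higher genes were also higher in control series 2 than in series 1 (256 if independent), a count added after the values were seen. PLS3 and LOC344887 were also the largest differences between the control series by the naming rule, so their difference cannot be given to the drugs here.

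Aciclovir lowered genes of the G2/M phase of the cell cycle. Of 19 such genes, 10 fell over all genes and 13 adjusted over the list alone (median log2 -0.60, adjusted p = 4.02e-18). HMMR, which helps to build the mitotic spindle, fell from 124 ± 34.8 to 51.8 ± 4.14 CPM (log2 -1.21, SE 0.10), the kinetochore motor gene CENPE by 1.12 ± 0.10 (log2, SE), ASPM, a spindle pole gene, by 1.08 ± 0.08 and the mitotic kinase gene AURKA by 0.98 ± 0.10. DNA replication genes rose for 3 of 20, and for 10 adjusted over the list alone (adjusted p = 0.000863). These were E2F1, a driver of entry into S phase (0.75, SE 0.11), the replication licensing gene CDT1 (0.59, SE 0.10) and the ribonucleotide reductase gene RRM2 (0.55, SE 0.07). The linker histone gene H1F0 (-1.14, SE 0.14) and the helicase gene PIF1 (-1.17, SE 0.18) were also among the 6 largest falls, as was HMMR-AS1 (-1.28, SE 0.16), which overlaps HMMR and is uncertain because the strand is not stated. With aciclovir 37 genes were called, 11 higher and 26 lower, against 64 with vehicle series 1 alone and 4153 with vehicle series 2 alone. The count was 23 without aciclovir replicate 3, and 21 or 23 without replicate 1 or 2 of vehicle series 1, but 350 (205 higher and 145 lower) in a fit of the 9 libraries compared alone and 91 without the pair of libraries that stand apart.

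With ribavirin, ribosome biogenesis genes were lower as a list (18 genes, median log2 -0.27), with 0 called over all genes and 3 lower adjusted over the list alone (adjusted p = 0.00387, and adjusted p = 0.109 with an estimated correlation). SLC7A11 fell from 85.3 ± 42.3 to 30.3 ± 3.73 CPM (log2 -1.33, SE 0.11), the noncoding RNA gene BCYRN1 by 1.12 ± 0.12 (log2, SE), the vault RNA gene VTRNA2-1 by 1.79 ± 0.31 and ZNF621 by 1.31 ± 0.23. SLC7A11 was also higher in control series 2 than in series 1, so the size of its fall depends on the vehicle series, which the SE does not cover. The phospholipid transporter gene ABCB4 rose from 9.09 ± 1 to 18.9 ± 3.52 CPM (log2 1.05, SE 0.18). With ribavirin 23 genes were called, 12 higher and 11 lower, against 418 with vehicle series 1 alone and 2647 with vehicle series 2 alone. Single libraries moved this count: it was 43, 8 and 4 without ribavirin replicates 1, 2 and 3, 10 and 8 without replicates 1 and 2 of vehicle series 1, and 13, 6 and 10 without replicates 1, 2 and 3 of vehicle series 2. A fit of the 9 libraries compared alone gave 157, and leaving out the pair of libraries that stand apart gave 158.

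The nucleoside analogues were compared directly, at concentrations that are not given and may differ. G2/M genes were lower with aciclovir for 14 of 19, and for 15 adjusted over the list alone (median log2 -0.44, adjusted p = 1.73e-19), with CENPE at -0.92 (95% interval -1.14 to -0.71), HMMR at -0.90 (-1.12 to -0.69) and ASPM at -0.70 (-0.87 to -0.52). DNA replication genes were higher for 4 of 20, among them CCNE1 (0.57) and PCNA (0.53), and adjusted over the list alone 6 were higher and 1 lower (adjusted p = 0.00227), while E2F1 (0.19, -0.07 to 0.45) and CDT1 (0.09, -0.14 to 0.32) were not called. Ribosome biogenesis genes were higher for 2 of 18 (POLR1B 0.43 and NOLC1 0.38), and for 4 adjusted over the list alone (adjusted p = 0.00192, and adjusted p = 0.0838 with an estimated correlation). Interferon-stimulated genes were lower for 4 of 24 (OAS1 -2.45, IRF7 -0.84, IFI6 -0.71 and OAS3 -0.69) and higher for OASL (0.456 ± 0.41 CPM, against no counts with ribavirin) by both adjustments (adjusted p = 0.0163, and adjusted p = 0.156 with an estimated correlation), and of 7 aryl hydrocarbon receptor targets CYP1B1 was lower (-0.75) by both adjustments (adjusted p = 0.0163). VTRNA2-1 (2.36, SE 0.32), C19orf57 (2.13, SE 0.35) and the protease gene HTRA3 (1.85, SE 0.28) were higher with aciclovir, beside HIF1A-AS1 (2.15) and SNAR-C3 (1.92), which are uncertain as an antisense gene and a repeated copy. PLA2G4C (-2.25, SE 0.42), GPC5 (-1.24, SE 0.23), SIGLEC11 (-1.15, SE 0.31) and ZNF429 (-1.13, SE 0.32) were lower, as was the uncertain HMMR-AS1 (-1.14, SE 0.18). In all, 901 genes differed, 389 higher and 512 lower with aciclovir, and 10569 of the 14741 genes not called had an interval within 2-fold either way. The count was 486 and 401 without aciclovir replicates 2 and 3, 531 and 304 without ribavirin replicates 2 and 3, and 1781 without the pair of libraries that stand apart. Of the 389 higher genes 192 were lower in control series 2 than in series 1 (58.9 if independent), and of the 512 lower genes 264 were higher there (76.8 if independent), a count added after the values were seen. The G2/M and interferon-stimulated lists were also called higher in control series 2. Aciclovir lay at -0.05 and ribavirin at 0.16 on the axis between the series, so a part from the series stays open for these lists. G2/M genes also fell with aciclovir against both vehicle series.

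Tofacitinib raised integrated stress response genes. Of 20, 13 rose over all genes and 14 adjusted over the list alone (median log2 0.97, adjusted p = 8e-17). STC2 rose by 3.32 ± 0.34 (log2, SE), CHAC1 from 4.31 ± 1.22 to 33.3 ± 4.06 CPM (2.95, SE 0.18), the mTOR inhibitor gene DDIT4 by 2.10 ± 0.17 and SESN2 by 1.90 ± 0.12. Cholesterol synthesis and uptake genes fell for 9 of 21, and for 11 adjusted over the list alone (median log2 -0.57, adjusted p = 6.45e-12), with MSMO1 at -1.15 ± 0.12 and INSIG1 at -0.98 ± 0.11. Ribosome biogenesis genes fell for 3 of 18 (GNL3 -0.63, UTP20 -0.63 and NOP16 -0.54), and for 4 adjusted over the list alone (adjusted p = 1.1e-05). DNA replication genes fell for 2 of 20 (MCM4 -0.39 and CDC6 -0.38), and for 3 adjusted over the list alone (adjusted p = 0.000793). Of 15 purine nucleotide synthesis genes ADSS fell (-0.47), and 4 fell adjusted over the list alone (adjusted p = 0.0167, and adjusted p = 0.0569 with an estimated correlation).

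Genes of JAK-STAT feedback, the pathway that tofacitinib inhibits, were not called as a list (16 genes, adjusted p = 0.976), and the interferon-induced GTPase gene GBP2 was the 1 member called (log2 1.09, SE 0.20). The Rab GTPase regulator gene TBC1D30 rose from 2.85 ± 0.882 to 33.6 ± 9.6 CPM (log2 3.56, SE 0.21) and AJUBA by 2.07 ± 0.44 (log2, SE). The transferrin receptor gene TFRC, which takes up iron, fell from 89.4 ± 14.1 to 35.7 ± 2 CPM (log2 -1.31, SE 0.11), beside DNA2 (-1.26), LOC101927078 (-1.69) and LOC101243545 (-1.57), while SMN1 (-1.54) and H3F3AP4 (-1.49) are near-identical copies and uncertain. With tofacitinib 363 genes were called, 171 higher and 192 lower, against 1725 with vehicle series 1 alone and 2952 with vehicle series 2 alone. The count was 214 without tofacitinib replicate 1 and 239 without replicate 2 of vehicle series 1, but 769 in a fit of the 9 libraries compared alone and 681 without the pair of libraries that stand apart.

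Sodium lauryl sulfate raised integrated stress response genes. Of 20 integrated stress response genes, 8 rose over all genes and 14 adjusted over the list alone (median log2 1.03, adjusted p = 1.58e-14), with CHAC1 at 3.05 ± 0.18 (log2, SE), STC2 at 2.73 ± 0.34, SESN2 at 1.85 ± 0.12 and the asparagine synthetase gene ASNS at 1.32 ± 0.17. PDK4, which turns cells from glucose to fatty acid oxidation, rose from 2.9 ± 0.728 to 32.3 ± 7.14 CPM (log2 3.50, SE 0.25), and PLIN2, which coats lipid droplets, from 89.5 ± 15.6 to 317 ± 13.1 CPM (1.84, SE 0.08). The cholesterol exporter gene ABCA1 fell from 26.2 ± 3.07 to 9.61 ± 0.36 CPM (log2 -1.44, SE 0.15). Immediate early genes were higher as a list (16 genes, median log2 0.47, adjusted p = 0.00757, and adjusted p = 0.12 with an estimated correlation), with 0 called over all genes, and 1 higher and 1 lower adjusted over the list alone. With sodium lauryl sulfate 48 genes were called, 44 higher and 4 lower, against 108 with vehicle series 1 alone, 2802 with vehicle series 2 alone and 140 in a fit of the 9 libraries compared alone. Of the 44 higher genes, 31 were also higher with tofacitinib (0.481 if independent), and of the 4 lower genes 2 were also lower (0.0491 if independent). Both chemicals share the vehicle libraries, and unchanged groups simulated against them had 0 genes called, so these give no comparison for the overlap. With a different vehicle series for each chemical, 53 higher genes were shared (7.92 if independent) and 2 lower (1.98), or 95 higher (68.8) and 61 lower (86.2) with the series exchanged.

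**Figure D4:**
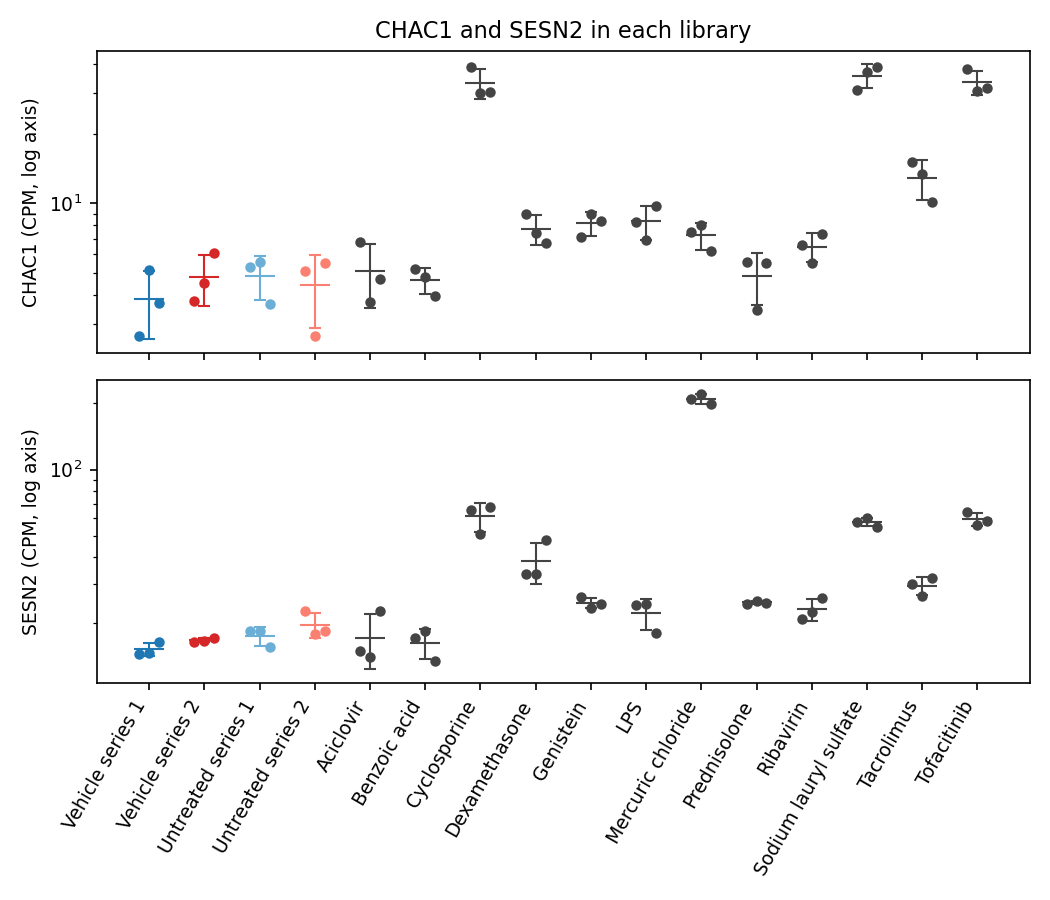
CPM of CHAC1 and SESN2 in each library (log axis), with the mean and SD of each group of 3. CHAC1 reached 35.7 CPM with sodium lauryl sulfate, 33.3 with tofacitinib, 33.1 with cyclosporine and 12.9 with tacrolimus.

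Mercuric chloride changed more genes than any other chemical here, led by metal and protein damage responses. All 9 metallothionein and zinc export genes tested rose by both adjustments (median log2 5.50, adjusted p = 2.69e-11), with MT2A, which binds mercury and zinc, going from 136 ± 39.1 to 10601 ± 248 CPM (6.33, SE 0.12). MT1M (9.58), MT1A (6.56) and MT1H (5.53) are near-identical copies and uncertain one by one. All 16 heat shock genes rose by both adjustments (median log2 2.79, adjusted p = 3.57e-17), among them the HSP70 cofactor gene DNAJB1, from 119 ± 17.9 to 6752 ± 676 CPM (5.84, SE 0.09). The small heat shock protein gene CRYAB had 2812 counts against 1 in the 6 vehicle libraries (ratio 11155, 95% counting interval 2000 to 440748). HSPA7 (12.65), HSPA6 (12.28), HSPA1A (8.64) and HSPA1B (7.63) are near-identical in pairs and uncertain one by one. Of 20 NRF2 genes, 16 rose by both adjustments (adjusted p = 6.04e-06, and adjusted p = 0.0744 with an estimated correlation), with HMOX1 going from 3.33 ± 1.78 to 1576 ± 126 CPM (8.91, SE 0.20).

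Immediate early genes rose with mercuric chloride for 15 of 16 by both adjustments (median log2 3.96, adjusted p = 6.82e-10), with EGR3 at 8.44 ± 0.66 (log2, SE), FOSB at 8.23 ± 0.38 and ATF3 at 7.33 ± 0.21. Integrated stress response genes rose for 13 of 20 and fell for 1, and adjusted over the list alone 15 rose and 1 fell (adjusted p = 3.31e-06), with PPP1R15A, which restarts translation after stress, at 5.77 ± 0.11. Endoplasmic reticulum chaperone genes rose for 12 of 16 by both adjustments (adjusted p = 0.000841), and cholesterol genes for 14 of 21 and 15 adjusted over the list alone (adjusted p = 0.000117), with HMGCS1 at 2.71 ± 0.09. NF-kB genes rose for 12 of 25 and fell for 1 by both adjustments (adjusted p = 0.0141, and adjusted p = 0.0647 with an estimated correlation), with the chemokine gene CCL3 at 6.41 ± 0.32. Glycolysis and hypoxia genes rose for 10 of 18 by both adjustments (adjusted p = 0.0357, and adjusted p = 0.368 with an estimated correlation), with the vasodilator gene ADM at 8.83 ± 0.56. DNA replication genes fell for 18 of 20 and rose for 1 by both adjustments (median log2 -0.84, adjusted p = 8.3e-06), the sliding clamp gene PCNA by 1.65 ± 0.16 and the helicase gene MCM3 by 1.55 ± 0.10. Purine nucleotide synthesis genes fell for 8 of 15 by both adjustments, with PFAS at -1.57 ± 0.18 (adjusted p = 0.0305, and adjusted p = 0.0744 with an estimated correlation).

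The chemokine receptor gene CCR2, which guides monocytes to inflamed tissue, fell from 125 ± 19.4 to 9.06 ± 1.3 CPM with mercuric chloride (log2 -3.77, SE 0.11) as did the matrix gene VCAN (log2 -3.18, SE 0.11). The other largest falls were FAM212A (-4.12), B3GNT8 (-4.03), RIMBP3C (-3.83) and NRON (-3.53). The other largest rises were the neurofilament gene NEFM (984 counts against 1, ratio 3903, counting interval 699 to 154331), LINC00624 (901 counts against 0, at least 1191-fold) and CTB-7E3.1 (354 counts against 0, at least 468-fold). Summed markers of other cell types stood at 37.7 ± 3.02 CPM for T cells (3.66 and 3.34 in vehicle series 1 and 2), 37.3 ± 1.92 for fibroblasts (6.39 and 5.66), 19.2 ± 3.45 for erythroid cells (0.423 and 0.524) and 10.5 ± 9.84 for epithelial cells (1.61 and 1.62), while those of B cells stood at 26.2 ± 1.11 (41.5 and 48.8). IL7R stood at 36.1 ± 3.62 CPM and the collagen gene COL1A1 at 30.5 ± 1.01 CPM (SD, n = 3), while HBA2 (14.9 ± 2.1 CPM) is a near-identical copy of HBA1 and uncertain. LCK (0.887 ± 0.111 CPM) and COL6A3 (1.26 ± 0.365 CPM) had no counts in the vehicle libraries, CD3E and COL3A1 had 0 counts with mercuric chloride, and the epithelial markers EPCAM and KRT18 stood at 1.74 ± 2.49 and 2.57 ± 3.62 CPM. The nuclear noncoding RNA MALAT1 stood at 26863 ± 1475 CPM against 8110 ± 414 and 11011 ± 231 in the vehicle series (SD, n = 3 each). With mercuric chloride 6549 genes were called, 3404 higher and 3145 lower, against 8985 with vehicle series 1 alone and 8221 with vehicle series 2 alone. TMM scaling takes most genes as unchanged, and its factors were 0.752 to 0.772 here against 0.959 to 1.06 in the other libraries. The balance of rises and falls, and the size of moderate changes, depend on that scaling. With every library thinned to 5.95 M counts, the mercuric chloride libraries kept counts in 18649 ± 118 symbols (SD, n = 3), against means of 15968 to 16557 in the other groups.

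**Figure D5:**
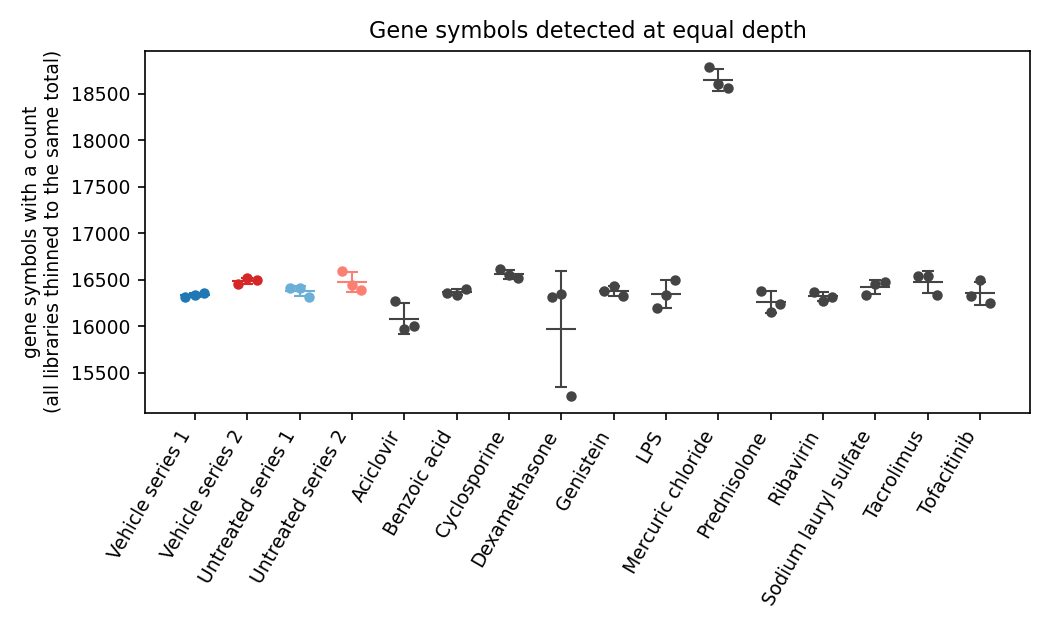
Gene symbols with at least 1 count in each library after thinning to the smallest total of 5.95 M, with the mean and SD of each group of 3. Mercuric chloride stands at 18649 symbols and vehicle series 1 at 16332.

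Genistein lowered ribosome biogenesis genes. The list of 18 had a median log2 of -0.37 (adjusted p = 1.82e-08), with 2 lower over all genes and 7 adjusted over the list alone. NOP16, a nucleolar protein gene, fell from 89.1 ± 4.75 to 61.5 ± 6.36 CPM (log2 -0.54, SE 0.09), and GNL3, the nucleostemin gene, by 0.41 ± 0.07 (log2, SE). The pseudokinase gene TRIB2 rose from 6.83 ± 0.735 to 13.9 ± 2.35 CPM (log2 1.03, SE 0.17), while the GABA receptor gene GABBR2 fell by 1.25 ± 0.18 and the receptor tyrosine kinase gene RET by 1.08 ± 0.15. With genistein 37 genes were called, 8 higher and 29 lower, against 280 with vehicle series 1 alone and 3208 with vehicle series 2 alone. Single libraries moved this count: it was 6, 13 and 8 without genistein replicates 1, 2 and 3, 13, 9 and 23 without replicates 1, 2 and 3 of vehicle series 1, and 23, 21 and 18 without replicates 1, 2 and 3 of vehicle series 2. It was 446 in a fit of the 9 libraries compared alone, 140 with the 6 vehicle libraries as 1 group, 120 without the pair of libraries that stand apart, and 58 and 70 by limma-voom and DESeq2.

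Benzoic acid raised immediate early genes. Of 16, 2 rose over all genes and 7 adjusted over the list alone (median log2 0.56, adjusted p = 5.4e-06). EGR1, a transcription factor gene switched on within minutes by growth signals, rose from 26.9 ± 9.76 to 84.8 ± 19.2 CPM (log2 1.71, SE 0.18), IER2 by 0.78 ± 0.09 (log2, SE) and TNF from 7.04 ± 1.95 to 19.7 ± 2.55 CPM (1.51, SE 0.18), the last in the major histocompatibility complex and so uncertain. The remaining called genes were the noncoding RNA gene NEAT1 (0.87, SE 0.11) and the mitochondrial protease gene YME1L1 (-0.59, SE 0.08), named because the count is short and chosen after their values were seen. With benzoic acid 5 genes were called, 4 higher and 1 lower, against 345 with vehicle series 1 alone and 834 with vehicle series 2 alone. The count was 3 and 2 without replicates 1 and 2 of vehicle series 1. Replicate 3 of benzoic acid stands apart: its 10 most abundant genes took 6.87% of the counts against 5.54% in each of the others, the nuclear RNA MALAT1 stood at 12935 ± 5615 CPM over the group (SD, n = 3), and without this library 4 genes were called.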

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

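Each count of called genes was set against other divisions of the same libraries, in fits of the compared libraries alone, only as to whether chance can be excluded. These divisions were planned, while 2 tests weighed below, that of the DMSO percentages and that of the depth of the mercuric chloride libraries, were chosen after the result was seen. For benzoic acid the real division called 2 genes, 1 of 100 divisions reached that (the real one included) and the highest other called 0. The same 1 of 100 held for dexamethasone (511 genes, highest other 284), genistein (446, highest other 7), LPS (1468, highest other 860) and mercuric chloride (7160, highest other 6424). In the dexamethasone and mercuric chloride cases the highest other kept the treated libraries together and divided the vehicle libraries differently. For control series 2 against series 1 it was also 1 of 100 (6145, highest other 2244). With vehicle against untreated libraries, 16 of 100 divisions called at least the 2 genes of the real one (highest other 87), so chance cannot be excluded there. In the treatment comparisons most divisions mix the vehicle series, and the difference between the series then enters the spread. The median of the other divisions was 0 in each. A high rank of the real division of a treatment therefore does not by itself exclude chance.

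In other treatments a division called more genes than the real one. It was 2 of 100 for aciclovir (350, highest other 3240), prednisolone (693, highest other 2731), sodium lauryl sulfate (140, highest other 2823), tacrolimus (42, highest other 2786) and tofacitinib (769, highest other 1043), and 3 of 100 for ribavirin (157, highest other 1833). Each of these highest divisions takes the 3 libraries of vehicle series 2 as the treated group. For cyclosporine it was 3 of 100 (401, highest other 3057), with the 3 libraries of vehicle series 1 in that place. These divisions point to structure among the samples, the difference between the vehicle series, which calls more genes than those treatments do in the same fits. For the direct comparisons 10 divisions exist, too few to exclude chance. The real ones, each 1 of 10, called 6 genes for dexamethasone against prednisolone, 4112 for cyclosporine against tacrolimus and 1002 for aciclovir against ribavirin, and the highest other called 0 in each.

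The first pattern weighed is the 4716 genes that differ between the control series. A difference in depth does not account for it, since 4634 genes were called after the control libraries were thinned to the smallest control total, 4497 of them shared. The DMSO percentages in the vehicle titles do not account for it as the whole cause, since 2225 genes differed between the untreated libraries alone. A batch of cells, of library preparation or of sequencing stays open, since the labels give none. The design holds no group that separates the series, so no biological explanation was tested.

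The second pattern is that mercuric chloride libraries hold counts in genes that are silent in the controls, 740 of 4595 (16.1%) against 0.174 to 1.74% in the other treatments. Deeper sequencing is excluded because these libraries hold the fewest counts (mean 6.41 M), while thinning all to the smallest total, which left at least 18564 symbols in each of them, could not have come out otherwise and adds nothing. Background spread evenly over silent genes would not depend on their neighbours. Such genes held counts more often where the next gene upstream is expressed (odds ratio 2.03, 95% interval 1.72 to 2.39). This association is not particular to mercuric chloride, with odds ratios of 1.33 to 3.23 among the few such genes in the other treatments. The genes were not matched for length, so a background that is uneven across genes stays open. Transcription that runs on from the gene upstream stays open: the odds ratio was 1.21 times that for the next gene downstream, and its interval of 0.947 to 1.55, which holds 1, also holds sizeable excesses. The treatment itself could be the cause in a way these data do not separate from RNA quality, which was not measured here, and the nuclear RNA MALAT1 also stood at 26863 ± 1475 CPM against 8110 and 11011 in the vehicle series.

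The third pattern is the rise of integrated stress response genes with cyclosporine, sodium lauryl sulfate, tacrolimus and tofacitinib. Vehicle libraries that are low by chance do not account for it, since the list was called higher against both untreated series in 4 of 4 treatments, with tacrolimus the nearest to the threshold (adjusted p = 0.0324, and adjusted p = 0.0677 with an estimated correlation). Position between the control series was weighed with the mix of the vehicle series at the treatment's own position. Against that mix the list was also called in 4 of 4. The mix gave series 2 a weight of 1.04 with cyclosporine, 0.047 with sodium lauryl sulfate, 0.026 with tacrolimus and 0.30 with tofacitinib. The list had already been called higher against each vehicle series, so this outcome was nearly fixed in advance and adds nothing. What a position between the series would not give is a call in the same direction against each of them. The biological explanation that the design gives is the treatment, and each of the 4 was set against the same controls. A loss of viability would be shared by the 12 chemicals, given at the same nominal viability, and the median log2 of the list against that mix was 0.90 with cyclosporine, 1.11 with sodium lauryl sulfate, 1.08 with tofacitinib, 0.49 with tacrolimus, 1.18 with mercuric chloride, 0.30 with dexamethasone and 0.13 with genistein, all 7 called higher there, and 0.01 with aciclovir and LPS, 0.05 with benzoic acid, -0.04 with prednisolone and -0.06 with ribavirin, which argues against an equal response to it in every treatment, while a part in the rise stays open because the viability reached is not given in the sources used here.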

How the results depend on the processing

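Each count of called genes was recomputed with the choices listed in the methods, fixed beforehand, and with 4 more chosen after seeing the data: the entries of a shared symbol kept apart, leaving out dexamethasone replicate 3 and benzoic acid replicate 3 together, leaving out mercuric chloride from the fit, and the libraries of the groups compared only. Of the named genes 0 reversed under any alternative. Genes named for a treatment were chosen with the same sign against both vehicle series. A reversal against either series alone was therefore impossible, and the other alternatives use much the same libraries. Their calls were lost in 215 cases and kept in 2011 when 1 library was left out, where a case is 1 gene in 1 comparison and setting. Calls were lost in 18 cases with untreated libraries, 10 with limma-voom, 10 with DESeq2 and 9 with the 6 vehicle libraries as 1 group. The number was 7 with the libraries compared only, 6 without the pair of libraries that stand apart and 5 with no filter. It was 5 with the treatment and both vehicle series only and 2 without mercuric chloride. Values outside 1.5 times the reported count follow, and the cause was not tested except where fewer libraries or a threshold on size act by construction.

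Against vehicle series 1 alone the counts were aciclovir 64, benzoic acid 345, cyclosporine 3762, dexamethasone 3345, genistein 280, LPS 2376, prednisolone 574, ribavirin 418, sodium lauryl sulfate 108, tacrolimus 37 and tofacitinib 1725, with 84 list calls. Against vehicle series 2 alone they were aciclovir 4153, benzoic acid 834, cyclosporine 218, dexamethasone 4718, genistein 3208, LPS 3772, prednisolone 3939, ribavirin 2647, sodium lauryl sulfate 2802, tacrolimus 2829 and tofacitinib 2952, with 122 list calls. With the 6 vehicle libraries as 1 group they were aciclovir 61, benzoic acid 1, cyclosporine 276, genistein 140, LPS 1990, prednisolone 622, ribavirin 87 and tofacitinib 995. With untreated in place of vehicle libraries aciclovir gave 60 and ribavirin 40. With the treatment and both vehicle series only in the fit they were aciclovir 350, benzoic acid 2, cyclosporine 401, dexamethasone 511, genistein 446, prednisolone 693, ribavirin 157, sodium lauryl sulfate 140, tacrolimus 42 and tofacitinib 769.

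A 2-fold threshold left aciclovir 6, benzoic acid 2, cyclosporine 31, dexamethasone 400, genistein 3, LPS 476, mercuric chloride 3322, prednisolone 127, ribavirin 5, sodium lauryl sulfate 19, tacrolimus 2 and tofacitinib 54, since it asks for a minimum size. With no filter genistein gave 14 and vehicle against untreated 2. With limma-voom genistein gave 58 and ribavirin 52, and with DESeq2 70 and 66. A 5 CPM filter gave 38 for ribavirin, and fry in place of camera gave 80 list calls against 43. Without the pair of libraries that stand apart the counts were aciclovir 91, cyclosporine 259, genistein 120, ribavirin 158, tacrolimus 19, tofacitinib 681 and aciclovir against ribavirin 1781, while dexamethasone gave 939 and dexamethasone against prednisolone 966. With the libraries compared only, dexamethasone against prednisolone gave 6 and vehicle against untreated 2.

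Leaving out 1 library at a time gave aciclovir 21 to 29, benzoic acid 2 to 5, cyclosporine 71 to 132, dexamethasone 832 to 1815, genistein 6 to 23, LPS 894 to 1000, mercuric chloride 5970 to 6505, prednisolone 228 to 260, ribavirin 4 to 43, sodium lauryl sulfate 36 to 44, tacrolimus 4 to 7 and tofacitinib 214 to 285. It gave 638 to 2346 for dexamethasone against prednisolone, 2101 to 2698 for cyclosporine against tacrolimus, 304 to 849 for aciclovir against ribavirin, 4165 to 4472 between the control series and 0 throughout for vehicle against untreated.

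Replicate numbers do not pair the libraries across groups: 360 pairs with the same number had a median residual correlation of -0.00327, and 11 of 48 libraries fitted best with their own number. With a replicate block the counts were aciclovir 30, benzoic acid 5, cyclosporine 130, dexamethasone 1306, genistein 35, LPS 1114, mercuric chloride 6527, prednisolone 296, ribavirin 22, sodium lauryl sulfate 47, tacrolimus 7 and tofacitinib 348. They were 1440, 3160 and 832 for the direct comparisons in the order above, 4696 between the control series and 0 for vehicle against untreated, with 43 list calls. In 3 cases the call of a named gene was lost. In the simulation, 40.3% of 1.5-fold changes were recovered with the treatment at vehicle series 1 and 23.9% midway between the series. Depth and the spread within a group were not varied.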

Other observations

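Several genes changed with more than 1 chemical, a reading across treatments that was chosen after the values were seen. SLC7A11, the cystine transporter gene, rose with cyclosporine (log2 1.38) and mercuric chloride (1.90) and fell with dexamethasone (-1.88), prednisolone (-1.80) and ribavirin (-1.33), and it was also higher in control series 2 (1.58). The size of each of these changes therefore depends on the vehicle series. TFRC, the transferrin receptor gene, fell with dexamethasone (-0.58), mercuric chloride (-1.18), tacrolimus (-0.98) and tofacitinib (-1.31). SERPINB2 fell with cyclosporine (-1.49), dexamethasone (-3.59), LPS (-2.62), mercuric chloride (-3.08) and prednisolone (-1.57). TSC22D3, a glucocorticoid receptor target, rose with dexamethasone (4.51) and prednisolone (3.56), and also with cyclosporine (0.88), mercuric chloride (2.63) and tofacitinib (1.66).

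PDK4 rose with dexamethasone (1.82) and sodium lauryl sulfate (3.50), and PLIN2 with dexamethasone (0.96), mercuric chloride (2.34) and sodium lauryl sulfate (1.84). CPT1A, which brings fatty acids into mitochondria, rose with sodium lauryl sulfate (0.79). ABCA1, the cholesterol exporter gene, fell with dexamethasone (-0.68), prednisolone (-0.74) and sodium lauryl sulfate (-1.44) and rose with cyclosporine (0.85). TBC1D30 rose with dexamethasone (2.84) and tofacitinib (3.56), and the cytokine receptor gene IL7R rose with LPS (3.35) and mercuric chloride (3.78) and fell with prednisolone (-1.51).

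The direct comparisons coincided in part with the difference between the control series, a count added after the values were seen. Of the 857 genes higher with dexamethasone than with prednisolone, 372 were higher in control series 2 (129 if independent) and 84 lower (130). Of the 587 lower genes, 226 were lower in series 2 (88.9) and 32 higher (88.0). Of the 1445 genes lower with cyclosporine than with tacrolimus, 1093 were lower in series 2 (219) and 0 higher (217). Of the genes that differ between aciclovir and ribavirin, 26 higher ones were also higher in series 2 (58.3) and 19 lower ones lower (77.6). With LPS the matrix gene DCN stood at 3.47 ± 1.37 CPM (SD, n = 3). With cyclosporine HBA1, a near-identical copy of HBA2 and so uncertain, was called, with 37 counts against 0 in the 6 vehicle libraries (1.39 ± 2.29 CPM, SD, n = 3).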
